A study of Homo sapiens with 21 samples.

How the data were processed

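The series holds 21 samples of MDA-MB-436 cells: 6 RNA-seq libraries (3 shScr, 3 shRNF8), 6 DRIP-seq libraries made with S9.6 antibody (2 shScr, 4 shRNF8), 6 RNase-treated DRIP-seq libraries (2 shScr, 4 shRNF8) and 3 input libraries. The kind of RNase is given in the labels only as a code. Files of 18 samples were used, and the inputs were not analysed here. Groups and replicate numbers were taken from the sample titles. Choices of groups, of the tests of the report, of gene lists, of the rule for named genes and of alternative settings were made before the data were examined. Depth matching, the tests on shScr replicate 1, on depth and on a separate processing run, and the test of DRIP peaks in the gene lists were exceptions, chosen after the data were seen.

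For RNA-seq the deposited table gives raw fragment counts per gene for 26485 genes, made with featureCounts from read pairs with an hg38 gene annotation, per the file headers. The command in the header sets no strand option, so reads of overlapping and antisense genes cannot be told apart. The labels describe polyadenylated RNA prepared with an mRNA-seq protocol. The submitters' processing notes list Trim Galore 0.6.6, STAR 2.7.9a, SAMtools 1.14, Subread 2.0.1, Bowtie2 2.2.6, Picard 2.10.9, MACS2 2.2.7.1 and deepTools 3.5.1 for the series and the build hg38, with no roles given.

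For DRIP-seq the authors deposited 1 peak list per library, with a fold enrichment of each peak over its local background (a linear ratio), and with -log10 of the p-value and of the q-value. The lowest -log10 q in the lists was 2.00 to 2.28. Peaks were called per sample, as the peak names within each list belong to 1 library. The names inside the lists of shRNF8 replicates 3 and 4 carry the stems of replicates 1 and 2 while the peaks differ. The total read depth of the DRIP libraries is unknown. For 8 of the 12 libraries (all 6 S9.6 libraries and the RNase-treated shRNF8 replicates 3 and 4) the fold and the p of every solvable peak gave a whole-number pileup that returned the deposited -log10 p to within 0.001, and the lowest local background that at least 5 of these peaks shared to within 1% served as a measure of depth.

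Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 14018 genes, libraries were scaled by TMM, and shRNF8 was compared with shScr by glmQLFit (robust) and glmQLFTest with the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 12.4%, and 2813 genes had an unadjusted p under 0.05. CPM values are TMM-scaled. On simulated counts for 13867 genes with 200 changed, the fit recovered 31 of 67 genes changed 1.5-fold (46.3%), 52 of 66 changed 2-fold (78.8%) and 64 of 65 changed 4-fold (98.5%), with 14 false calls. Fixed gene lists were tested with camera of limma 3.58.1 (correlation 0.01) on log-CPM values where at least 5 members were measured, with fry and an estimated correlation beside it. Of 38 lists, 35 were tested. The list of genes encoded in mitochondrial DNA had 0 measured members, and the immune marker list (4 measured) and the list of silent DRIP control genes (1 measured) were too small to test. For most of the 26 tested lists that camera did not call, the changed members or their number are given, and the results of a few members are not reported here.

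Peak lists were analysed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Peaks on chromosomes 1 to 22 and X were used. Peaks of the 6 S9.6 libraries were merged into regions when they shared at least 1 bp, and a region counted as called in a library with a peak inside it. Peak summits were assigned to gene starts (within 1000 bp), then gene ends (1000 bp before to 5000 bp after), exons, introns or intergenic sequence, with gene positions from the count table, in which 26023 of 26485 genes have 1 locus. On simulated peaks the merging found 200 of 200 regions placed only in shRNF8 and 100 of 100 placed only in shScr, and 100% of 3000 simulated pileups were recovered. Group differences were tested by two-sided exact permutation over all splits. For the comparison with RNase, labels were permuted within each hairpin. For shRNF8 against shScr there are 15 splits, so the smallest p is 0.0667. Depth matching scaled pileup and background to 0.698 background reads among the S9.6 libraries (0.620 with the RNase-treated libraries) and kept peaks with a -log10 p of at least 4. Peaks that were kept retained their deposited start and end.

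Named genes were RNF8 and XRN2, the 10 higher and 10 lower protein-coding genes with the largest log2 fold change among those called, with a mean CPM of at least 5 and no overlap of the groups, and up to 4 members with the smallest p of each list described. Named regions were the 5 only-shRNF8, 5 only-shScr and 3 shared regions with the highest mean fold, together with the DRIP control genes. RNF8 is itself 1 of the 10 lower genes.

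The alternatives tried for RNA were DESeq2 size factors, upper-quartile scaling, library size only, no filter, a mean CPM of at least 5, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each library. For DRIP they were a -log10 q or a fold of at least 5, equal peak numbers, all sequences, removal of peaks that overlap RNase-treated peaks, subsets of the shRNF8 replicates, other overlap and window rules, leaving out each library, and depth matching, which was added after seeing the data. No genome sequence was used here, so GC content was not checked.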

Results

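MDA-MB-436 is an established breast cancer cell line that carries a mutated BRCA1 gene. Cells transduced with a doxycycline-inducible lentiviral hairpin against RNF8 (shRNF8) were compared with cells carrying a control hairpin (shScr). RNF8 is a ubiquitin ligase of the DNA double-strand break response, and the series title concerns its modification of XRN2, an exonuclease of transcription termination, and the removal of R-loops, in which RNA pairs with DNA and displaces the other DNA strand. Polyadenylated RNA was sequenced in 3 shScr and 3 shRNF8 libraries. DNA-RNA hybrids were immunoprecipitated from sonicated chromatin with the hybrid-binding S9.6 antibody (DRIP-seq) in 2 shScr and 4 shRNF8 libraries, each with an RNase-treated library of the same number. The RNA libraries held 18121181 to 20006954 counts and between 17212 and 17835 detected genes. The S9.6 libraries held 32358 to 50963 peaks on chromosomes 1 to 22 and X. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

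The first comparison asked how mRNA differed between cells with the RNF8 hairpin and cells with the control hairpin. No further RNF8 hairpin and no rescue is labelled. Other effects of the hairpin, or differences between the transduced populations, thus cannot be told apart from loss of RNF8. RNF8 had 561, 537 and 553 counts in shScr replicates 1, 2 and 3, and 175, 195 and 142 counts in shRNF8 replicates 1, 2 and 3. Scaled to library size (CPM), the group means were 28.7 ± 0.585 CPM (SD, n = 3) and 9.09 ± 1.05 CPM (SD, n = 3), so that RNF8 was 3.15-fold lower in shRNF8 (log2 fold change -1.66, SE 0.13, adjusted p = 0.000165 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). XRN2 mRNA measured 144 ± 22.1 CPM in shScr and 160 ± 7.46 CPM in shRNF8 (n = 3 each), a log2 difference of 0.15 (SE 0.11) that did not pass the test (edgeR adjusted p = 0.468). XRN2 was 169 CPM in shScr replicate 1 against 138 and 126 CPM in replicates 2 and 3, and without replicate 1 its log2 fold change was 0.28 (edgeR adjusted p = 0.0165). Without that library 3865 of the 14018 genes tested passed, so this call was not particular to XRN2. With each library left out in turn, the log2 fold change of XRN2 ran from 0.0661 to 0.283 (edgeR adjusted p from 0.0165 to 0.875).

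**Figure D1:**
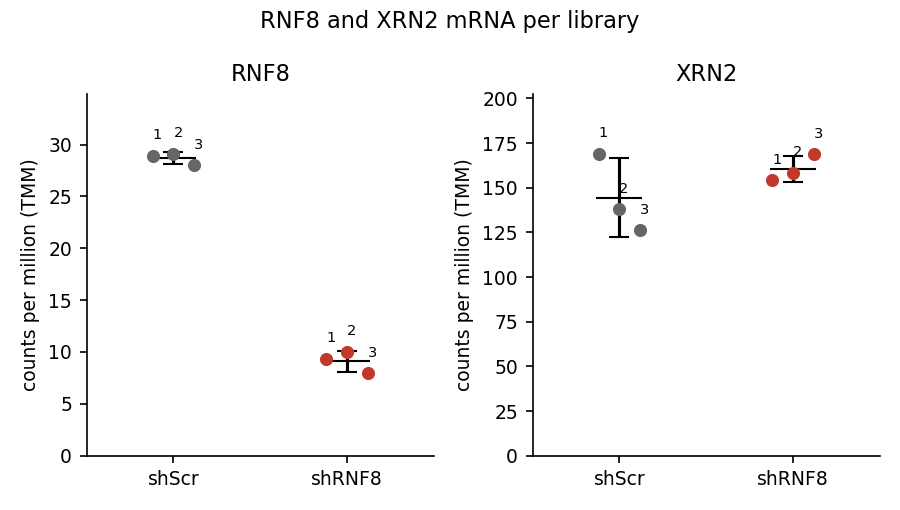
RNF8 and XRN2 mRNA in CPM (vertical axis) in each of the 3 shScr and 3 shRNF8 libraries (points, numbered by replicate), with the mean and SD of each group (bars). All shRNF8 libraries lay at or below 9.99 CPM for RNF8, while the XRN2 values of the groups overlapped.

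Among the genes higher in shRNF8, KRT75, a hair follicle keratin, had the largest named change, from 23.2 ± 10.6 CPM in shScr to 98.9 ± 12.2 CPM in shRNF8 (4.27-fold, n = 3 each, edgeR adjusted p = 0.0341). KRT75 did not pass without a filter on low counts or with the replicate number as a block (edgeR adjusted p = 0.112 and 0.129). NRP2, a co-receptor for semaphorins and VEGF family members, rose 3.96-fold from 2.12 ± 0.184 CPM in shScr (log2 fold change 1.99, SE 0.26, edgeR adjusted p = 0.00460). TRABD2A, a metalloprotease of the WNT pathway, rose 2.81-fold (log2 fold change 1.49, SE 0.15, edgeR adjusted p = 0.00126), and VGF, a secreted neuroendocrine protein, rose 2.23-fold from 324 ± 25.9 to 720 ± 97.2 CPM (edgeR adjusted p = 0.00126). The adhesion proteins CDH11 (2.79-fold, edgeR adjusted p = 0.00646) and CD24 (2.55-fold, edgeR adjusted p = 0.00488) were higher as well. CD274, which encodes the immune checkpoint ligand PD-L1, rose from 9.09 ± 2.43 to 20.5 ± 0.235 CPM (2.26-fold, edgeR adjusted p = 0.00821), and the lysosomal protease gene CTSS rose 2.45-fold (edgeR adjusted p = 0.00492). PKIB, an inhibitor of protein kinase A (2.99-fold, edgeR adjusted p = 0.00964), and UGT8, an enzyme of galactosylceramide synthesis (2.52-fold, edgeR adjusted p = 0.00646), completed the 10 highest.

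OLR1, a scavenger receptor for oxidised low-density lipoprotein, had the largest named decrease, from 68.0 ± 21.8 CPM in shScr to 15.5 ± 1.96 CPM in shRNF8 (4.38-fold lower, n = 3 each, edgeR adjusted p = 0.00396). PLCD3, a phospholipase C, went from 201 ± 11.1 to 73.5 ± 6.62 CPM (2.73-fold lower), and ZNF664, a zinc finger gene, from 160 ± 4.77 to 68.9 ± 3.05 CPM (2.31-fold lower). Both had an edgeR adjusted p of 0.000111. DDIT4, a stress-induced inhibitor of mTORC1, was 2.88-fold lower (edgeR adjusted p = 0.0250), and IGFBP3, which binds insulin-like growth factors, was 2.81-fold lower (edgeR adjusted p = 0.0363). The coagulation inhibitor gene TFPI (2.76-fold, edgeR adjusted p = 0.0217), the Arp2/3 inhibitor gene ARPIN (2.60-fold, edgeR adjusted p = 0.00516), the GDNF receptor gene GFRA1 (2.60-fold, edgeR adjusted p = 0.00994) and the procollagen peptidase gene ADAMTS2 (2.44-fold, edgeR adjusted p = 0.0362) were also lower. With limma-voom DDIT4, IGFBP3, TFPI and ADAMTS2 did not pass (adjusted p from 0.0671 to 0.0976). IGFBP3 and ADAMTS2 did not pass with library size only (edgeR adjusted p = 0.0525 and 0.0507), nor IGFBP3 and DDIT4 without a filter (edgeR adjusted p = 0.0502 and 0.111). In shScr replicate 1, OLR1 (43.0 CPM), DDIT4 (22.1 CPM) and GFRA1 (83.6 CPM) lay between the other shScr libraries and the shRNF8 libraries, whereas PLCD3 (214 CPM) and ZNF664 (162 CPM) did not.

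Of 14018 genes tested, 136 were higher and 220 were lower in shRNF8, of which 45 and 29 changed at least 2-fold. RNF8, NRP2, TRABD2A, VGF, OLR1, PLCD3 and ZNF664 passed whichever of the 6 libraries was left out. The remaining 13 of the 20 genes named above did not pass without 1 or more of the libraries, with edgeR adjusted p-values up to 0.189 (KRT75, without shScr replicate 3). The groups did not overlap in 25.3% of the genes, against the 10% that chance gives for 3 libraries against 3, and all 356 changed genes were among them. shScr replicate 1 differed from shScr replicates 2 and 3 by a chi-square per degree of freedom of 32.4 and 31.2, against 3.55 between replicates 2 and 3. On the first principal component (45.2% of the variance) it lay at -14.7, beside the shRNF8 libraries (-23.4 to -10.7) and away from shScr replicates 2 and 3 (31.2 and 30.4). Without it, 1823 genes were higher and 2042 lower, including all 356. Between 46 (without shRNF8 replicate 3) and 132 genes passed when any other library was left out. The DESeq2 Wald test called 324 higher and 535 lower genes, and edgeR without a filter on low counts called 267 and 381.

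**Figure D2:**
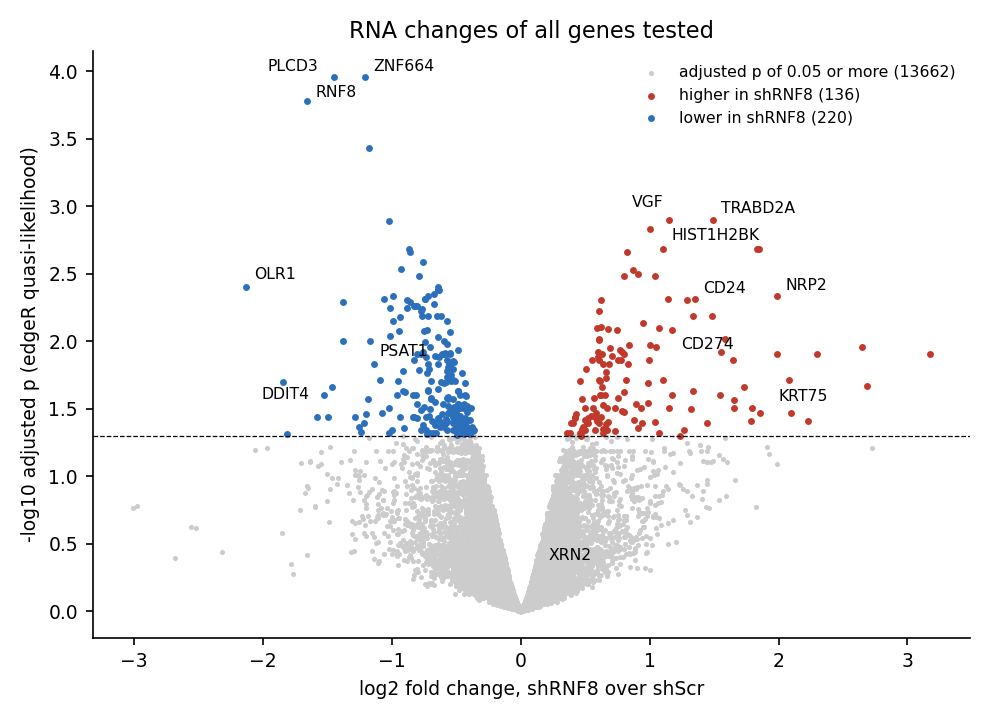
Log2 fold change of shRNF8 over shScr (horizontal axis) against -log10 of the adjusted p of edgeR's quasi-likelihood test (vertical axis) for the 14018 genes tested, 1 point per gene. The 136 higher and 220 lower genes lie above the dashed line at an adjusted p of 0.05, with PLCD3, ZNF664 and RNF8 at the top.

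Amino acid synthesis and stress genes driven by the transcription factor ATF4 were the group with the lowest p among the 35 gene lists tested. Of 27 measured members, 4 fell and 23 did not pass when adjusted over all genes, and 15 fell when adjusted over the list alone. The serine synthesis enzymes PSAT1 (208 ± 25.6 to 133 ± 14.3 CPM, 1.56-fold lower) and PHGDH (1.35-fold lower), the asparagine synthetase ASNS (1.63-fold lower) and DDIT4 were the 4. None of them passed without any 1 of the 5 libraries other than shScr replicate 1 (edgeR adjusted p from 0.0506 to 0.168). ASNS did not pass with library size only, nor DDIT4 with limma-voom, without a filter or with the replicate block. The median log2 fold change was -0.45 (camera adjusted p = 3.45e-07, and adjusted p = 0.546 with an estimated correlation), and fry, which asks whether the members moved on balance in one direction, gave an adjusted p of 0.0395. The mean level of the list in shScr replicate 1 was -0.29 on the log2 scale relative to the shScr mean, against 0.15 and 0.14 in shScr replicates 2 and 3 and -0.49 to -0.46 in shRNF8.

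Cholesterol synthesis genes had a median log2 fold change of -0.39 over 22 members (camera adjusted p = 0.000115, and adjusted p = 0.852 with an estimated correlation), which ran from -0.54 without shScr replicate 1 to -0.22 without shScr replicate 2. The squalene synthase gene FDFT1 fell (169 ± 41.0 to 106 ± 5.20 CPM, 1.60-fold lower, edgeR adjusted p = 0.0480), and adjusted over the list alone 3 members fell. FDFT1 did not pass with upper-quartile scaling, library size only, a mean CPM of at least 5 or limma-voom (adjusted p from 0.0611 to 0.0729, log2 fold change from -0.69 to -0.65), nor without any 1 library other than shScr replicate 1. DHCR7 (1.76-fold lower) and MVK (1.40-fold lower) did not pass over all genes. The list stood at -0.40 in shScr replicate 1, within the range of the shRNF8 libraries (-0.43 to -0.34), and at 0.28 and 0.12 in shScr replicates 2 and 3. Of 26 hypoxia and glycolysis genes, the angiogenic factor VEGFA (1.78-fold lower, edgeR adjusted p = 0.0139) and the glycolytic regulator PFKFB3 (1.51-fold lower, edgeR adjusted p = 0.0402) fell over all genes, and 3 fell and 1 rose adjusted over the list alone. VEGFA did not pass without shScr replicate 3 or any 1 of the shRNF8 libraries. PFKFB3 did not pass without any 1 library other than shScr replicate 1, with library size only or at a mean CPM of at least 5. The median was -0.26 (camera adjusted p = 0.0364, and adjusted p = 0.852 with an estimated correlation), and ran from -0.37 without shScr replicate 1 to -0.16 without shScr replicate 3. Here too shScr replicate 1 (-0.53) lay apart from shScr replicates 2 and 3 (0.23 and 0.29). The hypoxia list was not called without shScr replicate 2 or 3 or shRNF8 replicate 1 or 3 (camera adjusted p from 0.0960 to 0.215).

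None of 17 immediate-early genes changed when adjusted over all genes, and 5 fell and 1 rose adjusted over the list alone. Their median was -0.56 (camera adjusted p = 0.0134, and adjusted p = 0.852 with an estimated correlation), and JUND (1.70-fold), ATF3 (1.47-fold), NR4A1 (1.43-fold) and KLF4 (1.42-fold) had lower fitted levels. The list stood at 0.64 in shScr replicate 1 and at -0.38 and -0.25 in shScr replicates 2 and 3, and without replicate 1 its median was -0.09 (camera adjusted p = 0.754), with 4 members higher and 5 lower. JUND, ATF3, NR4A1 and KLF4 were lower without replicate 1 too (log2 fold changes -0.97, -0.44, -0.59 and -0.65, edgeR adjusted p from 9.82e-07 to 0.0240). In that setting 3865 genes passed. With all 6 libraries the edgeR adjusted p of these genes was 0.0652 to 0.0941. With each library left out in turn, it reached 0.242, 0.263, 0.314 and 0.346. Of 10 measured luminal epithelial markers none changed over all genes and 1 fell adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.0326, adjusted p = 0.546 with an estimated correlation, fry adjusted p = 0.0147). The list includes ELF3 (18.7 ± 3.94 to 12.1 ± 1.32 CPM) and MUC1 (2.84 ± 1.11 to 1.25 ± 0.541 CPM). Of 36 ribosomal protein genes, which share sequence with many processed pseudogenes, none changed by either adjustment, with a median of -0.12 (camera adjusted p = 0.0128, and adjusted p = 0.852 with an estimated correlation). Without shScr replicate 1 neither list was called. The luminal median was then -0.31 (camera adjusted p = 0.144), slightly larger in size, and the ribosomal protein median -0.06 (camera adjusted p = 0.157). The luminal list was also not called at a mean CPM of at least 5 (camera adjusted p = 0.165), with limma-voom (0.0527) or without shRNF8 replicate 1 or 3 (0.0645 and 0.0503), and the ribosomal protein list without shRNF8 replicate 1 or 2 (0.163 and 0.0659).

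Among higher groups, 2 of 5 measured replication histone genes rose by either adjustment. HIST1H2BK went from 12.2 ± 0.503 to 26.3 ± 2.65 CPM (2.15-fold, edgeR adjusted p = 0.00206) and HIST1H1C from 2.88 ± 0.0597 to 5.70 ± 0.778 CPM (1.98-fold, edgeR adjusted p = 0.0285), though HIST1H1C did not pass without any 1 library other than shScr replicate 1. Only polyadenylated transcripts were captured and histone genes have near-identical copies, so their counts are uncertain. The list had a median of 0.47 (camera adjusted p = 0.00831, adjusted p = 0.546 with an estimated correlation, fry adjusted p = 0.0358) and stood at 0.24 in shScr replicate 1. Over so few genes the median ran from 0.28 without shScr replicate 2 to 0.76 without shScr replicate 1. None of 36 S-phase genes such as RRM2 (699 ± 175 to 925 ± 73.0 CPM) and none of 18 MHC class I genes such as B2M (591 ± 54.7 to 749 ± 79.1 CPM) changed by either adjustment. The S-phase median was 0.12 (camera adjusted p = 0.0128, and adjusted p = 0.852 with an estimated correlation), with shScr replicate 1 at 0.23 and shRNF8 at 0.09 to 0.20. That median ran from 0.05 without shScr replicate 2 to 0.21 without shScr replicate 1. The MHC class I median, which includes paralogous HLA genes that share reads, was 0.18 (camera adjusted p = 0.0349, and adjusted p = 0.683 with an estimated correlation), with shScr replicate 1 at -0.15. S phase was not called without shScr replicate 2 or 3 or shRNF8 replicate 3 (camera adjusted p from 0.0503 to 0.238), nor MHC class I without shScr replicate 1 or shRNF8 replicate 1 or 2 (from 0.0604 to 0.283). Of the 9 lists, ATF4 targets, cholesterol synthesis and replication histones were called whichever library was left out. None of the 9 lists called by camera held with an estimated correlation, and 3 of the 9 also passed by fry. Among lists that camera did not call, fry called the apoptosis (fry adjusted p = 0.0147) and TGF-beta lists (fry adjusted p = 0.0395).

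**Figure D3:**
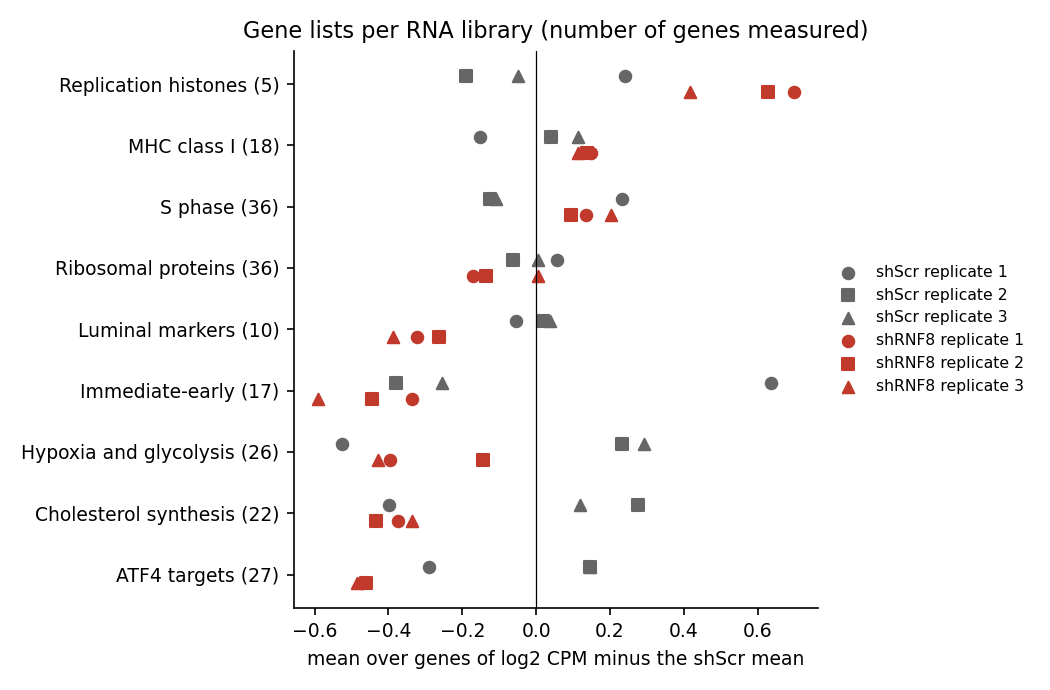
Mean log2 CPM of the members of the 9 lists called by camera (rows, with the number of genes measured), relative to the shScr mean, in each RNA library (horizontal axis; grey shScr, red shRNF8, shapes for replicates). shScr replicate 1 (grey circles) lay near the shRNF8 libraries for cholesterol synthesis (-0.40) and opposite to them for immediate-early genes (0.64).

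In the groups nearest to the question of the series, few genes changed. Of 20 measured genes of RNF8-dependent ubiquitin signalling only RNF8 fell by either adjustment. Of 33 R-loop factors, including the helicase gene DDX21 (log2 fold change -0.47, SE 0.12, edgeR adjusted p = 0.0631) and the FACT subunit gene SUPT16H (-0.39, SE 0.12, edgeR adjusted p = 0.0995), none changed by either adjustment. Nor did any of 27 termination, 16 THO/TREX, 23 homologous recombination or 16 Fanconi anaemia genes. Without shScr replicate 1, 10 of the R-loop factors were higher and 3 lower (camera adjusted p = 0.0336), and the camera adjusted p was 0.0132 for the termination list, 0.0233 for THO/TREX and 0.00135 for homologous recombination, all with positive medians. This gain was not particular to these lists. Without that library camera also called the NF-kB list (16 lower, adjusted p = 5.61e-05), G2 and mitosis (11 higher and 1 lower, adjusted p = 0.000656), the proteasome (7 higher, adjusted p = 0.00135) and heat shock genes (6 higher, adjusted p = 0.0233). None of these 8 calls was run with an estimated correlation. With all 6 libraries the estimated correlations of these lists were 0.19 to 0.74, and none passed with them (adjusted p from 0.852 to 0.890). Of 28 interferon-stimulated genes, HERC6 (1.56-fold, edgeR adjusted p = 0.0444) rose, and 4 rose adjusted over the list alone. The interferon list stood at -0.48 in shScr replicate 1 (camera adjusted p = 0.0561, and 0.962 without that library). In the nucleic acid sensing list the dNTP hydrolase gene SAMHD1 rose (1.39-fold, edgeR adjusted p = 0.0267), and in the TGF-beta list ID1 (2.25-fold lower, edgeR adjusted p = 0.00994) and BHLHE40 (1.56-fold lower, edgeR adjusted p = 0.00417) fell. Basal markers moved both ways, with MYLK (1.69-fold) higher and ITGB4 (1.71-fold) lower. Of 28 mesenchymal genes the protease inhibitor gene TIMP3 rose (1.79-fold) and the collagen gene COL4A1 fell (1.44-fold). The chemokine gene CXCL2 of the NF-kB list (1.43-fold), the ferritin gene FTH1 of the antioxidant list (1.35-fold, uncertain because it shares reads with processed copies) and IGFBP3 of the YAP list fell, each the only member that passed over all genes. None of 33 G2 and mitosis, 25 p53 target, 21 ATR checkpoint, 13 end joining, 16 ERK output, 12 heat shock, 30 proteasome, 27 respiratory chain or 23 autophagy genes changed by either adjustment with all 6 libraries. Of 20 unfolded protein response genes and 15 genes used as R-loop positive regions none changed over all genes, and 1 and 2 fell adjusted over the lists alone. Of 4 measured immune cell markers none changed over all genes, and 2 rose and 1 fell adjusted over the list alone.

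The second comparison asked whether the S9.6 peaks depended on RNase-sensitive material. The 6 S9.6 libraries held 32358 to 50963 peaks and the 6 RNase-treated libraries 254 to 1912, a 60.8-fold difference in the mean log2 number (exact permutation test within each hairpin, two-sided, p = 0.00476, the smallest that its 420 arrangements allow). The fold was 66.4 in shRNF8 (4 against 4 libraries, exact permutation p = 0.0286) and 51.1 in shScr (2 against 2 libraries, exact permutation p = 0.333, the smallest that 6 arrangements allow). Per numbered library the fold ranged from 26.7 (shRNF8 replicate 3) to 127 (shRNF8 replicate 1). The permutation tests did not treat libraries of the same number as pairs. Deviations of log2 peak number from the group mean had the same sign in both libraries of each shRNF8 number. In shScr the signs were opposite. Between 42.5% and 69.7% of the peaks of RNase-treated libraries were intergenic, against 8.46% to 11.04% of S9.6 peaks. Scaled to the same background depth, which could be recovered for the RNase-treated libraries of shRNF8 replicates 3 and 4 only, the S9.6 libraries of these numbers held 13.7-fold and 29.6-fold more peaks. The RNase-treated lists, already cut by q, lost no peaks in this step. Weaker RNase-treated peaks may be missing, so these folds may be too high.

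**Figure D4:**
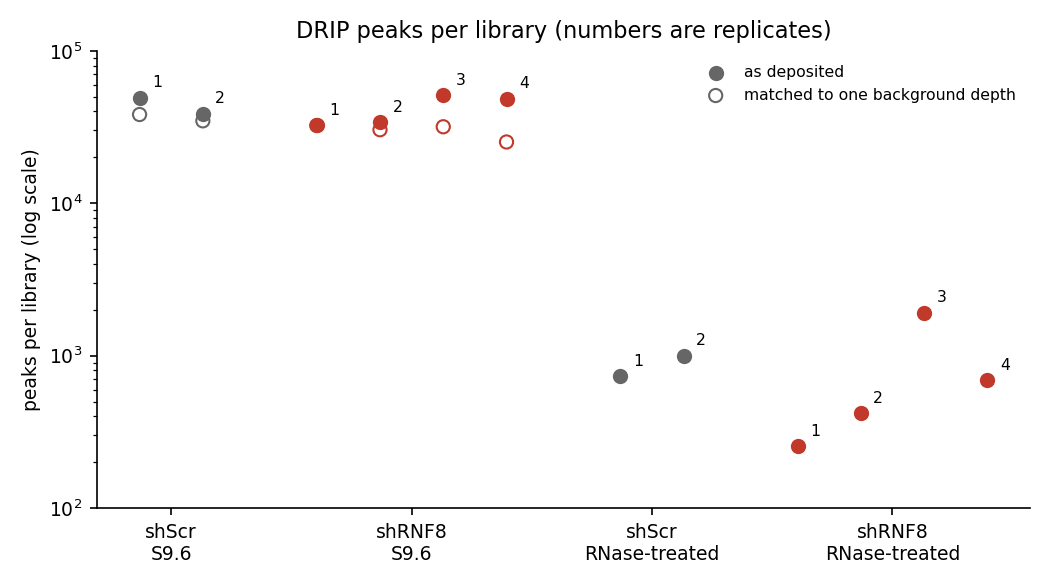
Number of peaks per library on a log scale (vertical axis) for S9.6 and RNase-treated libraries of shScr (grey) and shRNF8 (red), numbered by replicate. Filled points give the peaks as deposited (254 to 50963) and open points the S9.6 peaks left after scaling all S9.6 libraries to one background depth (25215 to 38167).

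Merging the S9.6 peaks gave 73564 regions, of which 8016 (10.9%) held a peak in all 6 libraries and 48.3% in 1 library. The fold of a region was the authors' fold enrichment of its highest peak in each library, averaged over the libraries that called it. Wide regions can hold more peaks, which can raise this value. Among the regions of all 6 libraries, the highest lay over the long noncoding RNA gene NEAT1 and the neighbouring FRMD8 (hg38 chromosome 11, 65412685 to 65450607, fold 60.3 ± 20.6). The next lay over the cluster from TNFSF12 to FXR2 that contains the translation factor gene EIF4A1 (chromosome 17, 7554641 to 7597605, fold 51.5 ± 16.4). Another lay over exons of TPPP (chromosome 5, 668386 to 678314, fold 50.4 ± 16.1, SD, n = 6 libraries each). The region at NEAT1 and FRMD8 also overlapped peaks of RNase-treated libraries, and with such peaks left out it held a peak in 66.7% of the S9.6 libraries. Of 15 genes commonly used as R-loop positive regions, 14 held a peak in all 6 libraries, including ACTB, RPL13A, CALM3 and APOE, and ING3 held one in 3 of 4 shRNF8 and 0 of 2 shScr libraries. For 13 of these genes a comparison with random lists matched on mRNA level and length was made. Of these, 12 held such a peak, against 8.97 in the matched lists (permutation adjusted p = 0.385). None of 7 genes chosen as silent in epithelial cells, such as HBB, MYOD1 and INS, held a peak in its body or the 5000 bp downstream, and the start window of TNNT2 held one in 1 shRNF8 library. RNF8 and XRN2 each held a peak in 2 shRNF8 libraries and 1 shScr library. Peaks were densest at gene starts, with 108 to 142 per Mb against 48.5 to 74.4 at gene ends and 14.8 to 25.7 in the rest of genes.

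The share of protein-coding genes with a peak in all 6 libraries rose with mRNA level. It was 9.44% of 5606 genes below the expression filter (95% Wilson interval 8.70 to 10.2, counting error only) and 24.7%, 35.4%, 45.3%, 56.9% and 72.8% in 5 equal classes of the measured genes from lowest to highest CPM (70.9 to 74.5 in the highest). The order was the same in short, middle and long genes, for example from 12.2% to 65.0% of long genes between the lowest and the highest class. These shares run over genes, which are not independent replicates.

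**Figure D5:**
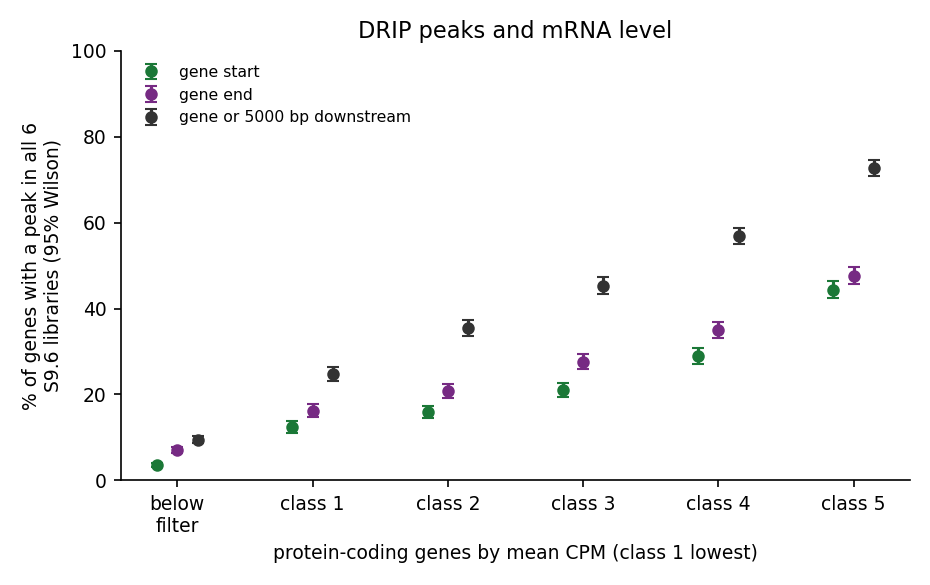
Percent of protein-coding genes with a peak in all 6 S9.6 libraries (vertical axis) at the gene start, at the gene end or anywhere in the gene or 5000 bp downstream, for genes below the expression filter and for 5 equal classes of the measured genes by mean CPM (horizontal axis), with 95% Wilson intervals. The share for the whole gene went from 9.44% below the filter to 72.8% in the highest class.

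The third comparison, named in the series design, set DRIP-seq of shRNF8 against shScr. Of 73564 regions, 537 held a peak in all 4 shRNF8 and neither shScr library, and 1835 held one in both shScr and no shRNF8 library. The only-shRNF8 regions with the highest fold lay in an exon of ATAD3A, a mitochondrial ATPase gene (chromosome 1, 1519707 to 1520190, fold 10.7 ± 3.68, SD over 4 libraries), at the start of HIGD1A (chromosome 3, 42802892 to 42805791, fold 10.2 ± 4.96), at the end of the pseudogene MSTO2P (chromosome 1, 155747703 to 155748118, fold 9.55 ± 2.82), across the glycerate kinase gene GLYCTK (chromosome 3, 52294712 to 52301809, fold 9.41 ± 2.80) and in the body of TOMM34 (chromosome 20, 44952405 to 44954977, fold 9.39 ± 5.53). ATAD3A and MSTO2P have close paralogs, so the placement of their reads is uncertain. The highest only-shScr regions lay at the end of SUPT16H (chromosome 14, 21352509 to 21352858, fold 11.7 ± 1.95, SD over 2 libraries), in an exon of FER1L4 (chromosome 20, 35605902 to 35606425, fold 11.3 ± 1.95), at the starts of TMEM126A (chromosome 11, 85647568 to 85648427, fold 11.1 ± 3.35) and of the pseudogene PRORSD1P (chromosome 2, 55281699 to 55282843, fold 10.4 ± 3.18), and at the end of C18orf8 (chromosome 18, 23525321 to 23528058, fold 10.4 ± 2.13). No region count has a test, and other splits of the 6 libraries into 4 and 2 gave up to 1800 regions in the 4 alone and up to 7550 in the 2 alone.

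As deposited, peak number did not separate the groups (43968 ± 7508 in shScr, n = 2, and 41493 ± 9617 in shRNF8, n = 4; log2 ratio -0.10, exact permutation p = 0.6). Scaled to one background depth, a setting added after the data were seen, shScr held 38167 and 34702 peaks. The shRNF8 libraries then held 32337, 30335, 31728 and 25215, each below both shScr libraries. A lower peak number does not mean less covered sequence, as peak widths differed. The mean deposited width was 966 and 1122 bp in shScr, and 1221, 1009, 1639 and 1628 bp in shRNF8 replicates 1 to 4. Peaks covered 47.6 and 43.4 Mb in the 2 shScr libraries and 59.1 ± 25.7 Mb in shRNF8 (SD, n = 4; difference of mean log2 values 0.27, exact permutation p = 0.733). Gene ends, where XRN2 acts, held 19.5% and 20.9% of the peak summits in the 2 shScr libraries and 18.1 ± 1.85% in shRNF8 (exact permutation p = 0.2), and gene starts held 13.5 ± 0.134% and 13.3 ± 2.92% (exact permutation p = 0.933). All these tests were two-sided, and 15 splits of 4 against 2 libraries cannot give a p under 0.0667. shRNF8 replicates 1 and 2 covered 39.5 and 34.4 Mb and replicates 3 and 4 covered 83.5 and 79.0 Mb, so the log2 ratio to shScr was -0.30 with replicates 1 and 2 alone. With replicates 1 and 2 alone 1713 regions were only in shRNF8, and with replicates 3 and 4 alone 9926 were. Background reads per peak position went with peak number across the 6 libraries (r = 0.911, exact permutation p = 0.0431; rho = 0.771, exact permutation p = 0.103; r = 0.902 without the 2 libraries farthest from the median; 1 relation computed), with 1.36 and 1.48 reads in shRNF8 replicates 3 and 4 and 0.698 and 0.948 in replicates 1 and 2.

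The last comparison joined both assays and asked whether genes with hairpin-specific regions changed in mRNA. The 467 measured genes with only-shRNF8 regions had a median log2 fold change of -0.01 relative to other genes (camera p = 0.389, and p = 0.742 with an estimated correlation), with 2 higher and 11 lower. The 2 higher were the membrane receptor gene DCBLD2 and the caspase-8 regulator gene CFLAR. DCBLD2 also held an only-shScr region (chromosome 3, 98868815 to 98869664), and the lower genes TNS3 and FAM53B likewise held regions of both kinds. PLCD3, with a region inside the gene (chromosome 17, 45125329 to 45126027, fold 4.68 ± 1.05), and ZNF664 (chromosome 12, 124001621 to 124003117, fold 4.26 ± 1.00) were among the 11 lower. The 1187 measured genes with only-shScr regions included 7 higher and 33 lower genes, among them PSAT1 and the hypoxia-inducible factor gene EPAS1 (1.67-fold lower, edgeR adjusted p = 0.00488), and their median was -0.03 relative to other genes (camera p = 0.237, and p = 0.493 with an estimated correlation). Changed genes made up 2.78% of the first set against 2.53% of other genes, and 3.37% of the second against 2.46%. The other genes were not matched on mRNA level or length, and whether these contribute to the shares or medians was not tested. With peaks of a fold of at least 5 the medians were -0.05 and -0.06 (camera p = 0.0498 and p = 0.0162, not run with an estimated correlation). For only-shScr regions 5 of 31 alternatives passed an unadjusted threshold of 0.05 by camera. Besides that fold these were a -log10 q of at least 5 (median -0.06), shRNF8 replicates 1 and 2 alone (-0.05), the same replicates after depth matching (-0.05) and leaving out shScr replicate 1 of the RNA-seq (-0.06). DCBLD2, CFLAR, TNS3, FAM53B, PLCD3, ZNF664, PSAT1 and EPAS1 were named here after their values were seen, apart from their place in the RNA comparison.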

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

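Of 18 sets of 4 values tested for a sample far from the others, 0 met the criterion, where chance gives 0.9. The tests on shScr replicate 1, on depth and on a separate processing run were chosen only after the results were seen.

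shScr replicate 1 of the RNA-seq stood apart from the other shScr libraries. In 6 of the 9 called lists it lay on the shRNF8 side of shScr replicates 2 and 3, by more than the gap between these, for example at -0.29 for ATF4 targets and -0.40 for cholesterol genes. A library on that side cannot make such a difference, which argues against it as the source for these 6 lists. Of these, 5 were still called without it, but leaving out such a library widens the difference by construction. For cholesterol (-0.397 against a shRNF8 mean of -0.381), hypoxia (-0.526 against -0.322) and S phase (0.233 against 0.144) it passed the shRNF8 mean. Those differences rest on shScr replicates 2 and 3, and whether these are their source was not tested. The luminal list was not called without shScr replicate 1, although its median was -0.308 without it and -0.272 with it. In the other 3 lists it lay on the opposite side, and none of them was called without it. For the shift of the immediate-early list as a whole it remains a candidate source, since the median without it was -0.0932. That does not extend to JUND, ATF3, NR4A1 and KLF4, which were lower without it as well (log2 fold changes -0.97, -0.44, -0.59 and -0.65). Whether it made the MHC class I and ribosomal protein lists move stays open, since their medians without it were 0.104 and -0.0632, against 0.179 and -0.119 with it. FOS, EGR1 and FOSB, named after their values were seen, had 1430, 2250 and 599 counts in shScr replicate 1, against at most 96, 277 and 72 in shScr replicates 2 and 3 and at most 163, 347 and 60 in shRNF8. A handling or culture difference of that library may be involved, and no label gives a batch with which to test it.

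shRNF8 replicates 3 and 4 of the DRIP-seq had more and wider peaks than replicates 1 and 2 (log2 ratio of peak number 0.58). After depth matching the log2 ratio of peak number was -0.147, which leaves background depth as a candidate source of the extra peaks. Covered bases kept a log2 ratio of 0.94, but the matching removed whole peaks and left the width of the others unchanged. It thus cannot show whether the wider peaks came from depth. The matched Jaccard overlap of replicates 3 and 4 was 0.686, against 0.369 to 0.431 with any other library, whereas replicates 1 and 2 overlapped the shScr libraries at 0.452 to 0.485. These overlaps also rest on the deposited widths, so depth may contribute to them. The peak names of replicates 3 and 4 repeat the stems of replicates 1 and 2 in place of their own numbers, so a separate processing run is a candidate explanation. No shScr library has the number 3 or 4, and a biological difference between these replicates was not tested.

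The RNase-treated libraries of shRNF8 replicates 3 and 4 had 0.706 and 0.620 background reads, against 1.36 and 1.48 in their S9.6 libraries. The depth-matched log2 ratio was 4.50, from 4 S9.6 and 2 RNase-treated shRNF8 libraries. The RNase-treated lists, already cut by q, lost no peaks in the matching (replicate 3 kept 1912), while S9.6 replicate 3 fell from 50963 to 26271. Weaker RNase-treated peaks may be missing, so the ratio may be too high. It does not settle how much lower depth contributed in shRNF8. No shScr library entered the ratio. Its p of 0.0667 by exact permutation is the smallest that 15 arrangements allow.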

How the results depend on the processing

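The depth-matched and single-subset depth-matched settings were chosen only after the data were seen. The alternatives kept the side of the threshold for most results, and the cause was not tested where they did not, unless a sentence gives it. The exact permutation tests of shRNF8 against shScr in DRIP-seq cannot give a p under 0.0667. They could not change side, so their share of unchanged results says nothing about robustness. Without a filter 267 genes were higher and 381 lower, with the DESeq2 Wald test 324 and 535, and with the replicate block 205 and 296, against 136 and 220. The replicate numbers gave no evidence of pairing (correlations of same-numbered deviations -0.05, 0.11 and -0.23), and KRT75 and DDIT4 were among the genes not called under the block. Leaving out 1 library gave 17 to 1823 higher and 29 to 2042 lower genes, a log2 fold change of XRN2 from 0.0661 to 0.283 (adjusted p 0.0165 to 0.875) and 5 to 13 called lists. An estimated correlation gave 0 called lists and fry 5. Scaling by library size alone kept 81.7% of the 356 calls, the lowest of the scalings. Among the other alternatives for named genes 389 of 429 values kept their side of the threshold, 18 fell below and 22 rose above it, and with 1 library left out 228 of 324 did, 72 fell below and 24 rose above. None changed direction.

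For DRIP-seq, depth matching gave a log2 ratio of S9.6 to RNase-treated peaks of 4.50, from 4 S9.6 and 2 RNase-treated shRNF8 libraries and no shScr library. This ratio may be too high, as weaker RNase-treated peaks may be missing from the lists. The log2 ratio of peak number of shRNF8 over shScr was 0.19 with replicates 3 and 4 only, and -0.278 to 0.0724 with 1 library left out. After depth matching the shScr libraries held 34702 and 38167 peaks and the shRNF8 libraries 25215 to 32337, without overlap. Peak number does not measure covered sequence, as the deposited mean peak width differed. It was 966 and 1122 bp in shScr, 1221 and 1009 bp in shRNF8 replicates 1 and 2, and 1639 and 1628 bp in replicates 3 and 4. The log2 ratio of covered bases was -0.30 with replicates 1 and 2 only and -0.23 with these after depth matching, which keeps peak widths. Regions only in shRNF8 numbered 333 at a -log10 q of at least 5, 340 at a fold of at least 5, 1713 with replicates 1 and 2 and 9926 with replicates 3 and 4 (1992 and 4077 after depth matching), 2399 with 3 of 4 libraries, and 714 to 1548 with 1 library left out. Regions only in shScr numbered 6334 and 2802 with these pairs (4811 and 3490 after depth matching), 3433 with at most 1 of 4 shRNF8 libraries, and 2095 to 8857 with 1 library left out. With fewer libraries these criteria are easier to meet by construction. The difference at gene starts was 0.0887 points at a fold of at least 5, 0.00190 after depth matching, 2.31 with replicates 1 and 2 (1.83 after depth matching), 0.442 with 2000 bp windows, and -1.21 to 0.745 with 1 library left out. Equal peak numbers make the peak-number ratio 0 by construction and give no value for it. The named region at FRMD8 held a peak in 66.7% of libraries once peaks that overlap RNase-treated peaks were left out. Named regions were chosen for being called in all libraries of a group, so leaving out a library or taking a subset cannot move them.

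The median RNA difference of genes with only-shRNF8 regions was -0.0528 at a fold of at least 5, and -0.0358 to 0.0158 with 1 library left out. That of genes with only-shScr regions was -0.0578 at a -log10 q of at least 5, -0.0603 at a fold of at least 5, -0.0517 with replicates 1 and 2 and -0.0522 with these after depth matching, and -0.0603 to -0.00915 with 1 library left out. The difference for only-shScr regions passed the threshold in 5 of 31 alternatives, namely these 4 settings and leaving out shScr replicate 1 of the RNA-seq (unadjusted p 0.0123 to 0.0465 by limma's camera), and that for only-shRNF8 regions in 1 of 31. On counts simulated at the depth of these libraries 46.3% of 1.5-fold changes were recovered, and how far depth limits this was not tested.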

Other observations

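The tests of copy number, gene length and other splits of the samples were planned before their results were seen, and the test of DRIP peaks in the gene lists was chosen only after peaks were seen to go with mRNA level.

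Genes of G2 and mitosis held S9.6 peaks less often than other genes of like mRNA level and length. Of 33 measured members 12 held a peak in all 6 S9.6 libraries, against 23.7 in 10000 random lists matched on both (permutation p = 2.0e-04, the smallest the random lists can give, adjusted p = 0.00680 over 34 lists). Homologous recombination genes (4 of 23, 9.88 in matched lists) and interferon-stimulated genes (7 of 27, 13.5 in matched lists) both had an adjusted p of 0.165 and did not pass. Of 36 ribosomal protein genes 31 held such a peak (29.3 in matched lists), and so did 19 of 33 R-loop factors (18.6 in matched lists).

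PLCD3, ZNF664, RNF8 and TBC1D10B had the lowest p of all genes tested. TBC1D10B, a GTPase activator for Rab proteins named after its values were seen, had a log2 fold change of -1.18 (SE 0.10, edgeR adjusted p = 0.000369). It had 1469 to 1809 counts in the shScr libraries and 671 to 769 in the shRNF8 libraries. The cell cycle inhibitor gene CDKN1B (log2 fold change -0.76, edgeR adjusted p = 0.00259) and the growth factor gene PDGFA (-0.86, edgeR adjusted p = 0.00206) were also lower, and the transcription factor gene NFATC2 (1.84, edgeR adjusted p = 0.00206) and the neuronal filament gene NEFL (0.87, edgeR adjusted p = 0.00295) were higher. These genes too were named after their values were seen.

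The 6 RNA libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 356 genes, 1 of the 10 reached that number, and the highest of the others called 0.

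A difference in copy number between the cell populations was tested through neighbouring genes. The correlation of the log2 fold changes of adjacent genes was 0.0609, above the highest of 1000 shuffles (0.0252). It was below the 0.1 that copy number differences were taken to need before the test. Adjacent genes thus changed together more than in the shuffles. A correlation over all genes cannot exclude copy number differences of single segments, so copy number stays open. The lowest median of 25 adjacent genes was -0.34 on chromosome 19 (17555702 to 18543596), where 4 genes were called. Chromosome 19 also had the lowest median of all chromosomes, -0.07. Gene length bias is argued against by a rho of -0.0580 between log2 fold change and exonic length over genes, which are not independent replicates.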
